A study of Homo sapiens with 40 samples.

How the data were processed

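The samples were 40 hybridisations of 2-colour lymphochip arrays, a spotted cDNA array built for lymphoid genes. Myeloma and lymphoma cell lines carried a retroviral, doxycycline-inducible shRNA against CASP10. Per the labels, RNA of cells induced with 20 ng/ml doxycycline was labelled with Cy5 and RNA of uninduced cells of the same day with Cy3, and 50 µg of total RNA was labelled for each dye. On 4 SKMM1 arrays the Cy3 channel held RNA of induced cells with a control shRNA in place of uninduced cells. The values are log ratios that the authors deposited as already processed, 1 per probe and array for 15246 probes with 0 missing values, and they were read as log2 ratios of the 2 channels. The base of the logarithm, the background correction and any normalisation are not given in the sources used here. The sign was taken as Cy5 over Cy3, so that a value above 0 is higher in induced cells; the dyes are stated in the labels, while the direction of the ratio is likely but not stated. No scanner intensities were used, so signal over background is unknown. All arrays had the same dye orientation, so a dye effect is part of every response against 0 and cancels only in differences between sets of arrays.

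The median log ratio of each array shows that the deposited values were not centred on the median. In SKMM1 the medians were -0.06, 0.074, 0.038 and 0.014 on days 1 to 4 of repeat 1, -0.79, -0.483, -0.302 and -0.44 on days 2 to 5 of repeat 2, and 0.082, 0.305, 0.36 and 0.145 on days 2 to 5 of repeat 3. The H929 medians were -2.15, -0.39, -0.109 and -0.026 on days 1 to 4 of repeat 1, 0.036, 0.035, 0.0015 and 0.027 on days 2 to 5 of repeat 2, and -0.27, -0.287, -0.026 and -0.001 on days 2 to 5 with shCasp10-3. The KMS12 medians were -0.231, -0.289, -0.113 and -0.035 on days 1 to 4 with shCasp10-2, and -0.07, -0.07, -0.005 and -0.004 on days 2 to 5 with shCasp10-3. On days 3 and 4 they were 0.213 and 0.073 for OCI-Ly7 and 0.012 and -0.009 for OCI-Ly19, and against the control shRNA they were 0.018, 0.047, 0.014 and 0.034 on days 1 to 4. Pearson's r over all probes was under -0.3 for 87 of the 780 pairs of arrays, 21 of them from different courses of the same line, hairpin and reference. The lowest, -0.517, was between the day 5 arrays placed in SKMM1 repeats 2 and 3, whose labels read repeats 1 and 2. Apart from the repeat number they differ in no condition that the labels state. The wide tail of repeat 2 is negative and that of repeat 3 positive. The labels state the same dyes for both and the ratios were kept as deposited. On each array of repeat 3, whose medians were above 0, 5 of the 6 CASP10 probes were below 0 and 1 was above. For this gene that argues against a turned sign of repeat 3. In repeat 2, 5 or 6 of the probes were below 0, but so were the array medians, so the values do not settle its direction. With all arrays, limma called 0 features in the myeloma response with the sign of repeat 2 turned (241 at an unadjusted p under 0.05). It called 0 with that of repeat 3 turned (1152 at an unadjusted p under 0.05). No comparison of all arrays gained a call. Turning repeat 2 moved the unadjusted counts, from 246 to 2497 in SKMM1 and from 40 to 2476 between SKMM1 and H929. They rose from 75 to 1686 between SKMM1 and KMS12 and fell from 1066 to 392 for the change with day. Camera then called 2 lists, both lower, in place of 2 higher and 2 lower. Counts without the wide arrays stand in the report. Within a course the median r was 0.404, and between myeloma arrays of different courses it was 0.032.

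Probes were named through the platform annotation that came with the values, which is old. A single gene symbol was listed for 10169 probes, several for 4, and 5073 were not listed and stay unnamed here. Entrez identifiers of 10128 probes matched the RefSeq gene table of GRCh38.p14, and 0 symbols changed. Probes of a gene were averaged and the others kept one by one, which gave 9681 features, of which 4604 were named genes, 2674 of them with more than 1 probe. No coordinates are given.

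The replicate was the time course: the days of 1 line, 1 hairpin and 1 repeat number. Where no repeat number in the label fitted a course, the run of consecutive database numbers placed the array. This was so for day 5 of SKMM1 repeats 2 and 3, labelled repeats 1 and 2. It was also so for day 1 of SKMM1 repeat 1, day 1 of H929 repeat 1 and day 5 of H929 repeat 2, whose labels give no repeat number. There were 8 myeloma courses of 32 arrays, 2 lymphoma courses of 4 arrays and 1 course of 4 arrays against the control shRNA. Days of a course may come from a single culture, and where the labels mark no separate cultures the p-values measure only the spread between these samples. Each course was averaged over days 2 to 4 (days 3 and 4 for differences from lymphoma) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the 3 myeloma lines weighted equally and Benjamini-Hochberg adjustment at 0.05. The fits on course means of all arrays, most of the other settings listed below, the 24 gene lists and the rule for naming genes were set before the data were examined. The rule named CASP10, the 10 highest and 10 lowest myeloma responses among named genes past the threshold with 1 sign in all courses, the members of each list with the smallest p, and for the other comparisons the 5 largest and 5 smallest differences past the threshold, or where none passed the 3 smallest p. A gene the annotation gives under a mouse-style symbol is not printed, and genes of the lymphoma response alone are named only with all arrays.

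After the values were seen, 12 arrays with over 10% of probes beyond 3 in log ratio were called wide arrays, and each comparison was fitted again without them, once on course means and once on single arrays with the course as a random block (duplicateCorrelation, consensus correlation 0.249). In myeloma this used 16 of 24 arrays from 7 courses. Every result described as "without the wide arrays" was therefore chosen after seeing the data, and the naming rule was applied there with 7 courses in place of 8. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, on course means in both settings, while calls of single members without the wide arrays come from single arrays. For each list with at least 5 measured genes the median log ratio relative to the array median was also compared over courses with a two-sided exact sign-flip test, which was added after seeing the data, as were array weights, features within 2 of 0 on every array, crossed repeat numbers and turned signs. The lists were caspase-10 and death receptor pathway, BCL2 family, autophagy machinery, lysosome, amino acid and integrated stress response, unfolded protein response and secretory pathway, cholesterol and fatty acid synthesis, glycolysis and hypoxia, FOXO targets, p53 targets, proliferation, MYC targets and ribosome biogenesis, ribosomal proteins, proteasome, oxidative phosphorylation, heat shock, IRF4 and plasma cell genes, NF-kB targets, interferon response, histones, and markers of mature B cells, of T and NK cells, of myeloid cells and of erythroid cells and platelets.

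The fits were tested in 5 simulations of the myeloma response over 9681 features, 200 of them changed in each. Values were drawn as normal, with the spread of each feature over the myeloma arrays that were not wide, scaled to the spread of each array. The one-sided tails and shifted medians of the wide arrays were not simulated, so the shares below need not hold for the real arrays. On course means of all arrays, 1.49% of changes of 0.5, 49% of changes of 1 and 88.8% of changes of 2 were called, and 4 of 470 calls were false. Without the wide arrays, on single arrays, the shares were 47.5%, 89% and 99.1%, and 67 of 923 calls were false. A list of 25 genes shifted by 0.5 was called by camera in 5 of 5 simulations, and 0 of 115 unshifted lists were; the simulated genes were independent. Alternatives were median centring of each array, single probes, single arrays, line means, other days, a single hairpin, a stricter threshold, robust eBayes, scaling of the arrays, array weights, the repeat number as a block, and leaving out each course or line. Runs of consecutive database numbers in the labels were used as a possible batch: 7 runs held the 11 courses. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and drew the plots. No array was excluded for its quality from the planned fits. Days 1 and 5 entered no main fit of a response. They entered alternatives over all days, some of them planned, the plots, and the values and tallies given per array.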

Results

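Caspase-10 was knocked down in multiple myeloma cell lines to find the genes that respond to its loss, with lymphoma lines as controls. SKMM1, H929 and KMS12 are human myeloma lines, that is, malignant plasma cells, and OCI-Ly7 and OCI-Ly19 are human B-cell lymphoma lines. Each array compared cells induced to express an shRNA against CASP10 for 24 to 120 hours with uninduced cells of the same line and day. The shRNA shCasp10-2 was used in SKMM1 (12 arrays, 3 repeats), H929 (8 arrays, 2 repeats), KMS12 (4 arrays), OCI-Ly7 (2 arrays) and OCI-Ly19 (2 arrays), and shCasp10-3 in H929 (4 arrays) and KMS12 (4 arrays). A further 4 arrays compared SKMM1 with shCasp10-2 with SKMM1 induced to express a control shRNA. Values are log2 ratios, given as the mean with the standard error (SE) of the fit or the SD over courses; their precision is limited by the number of arrays.

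The arrays differed widely in spread. On 12 of the 40 arrays, over 10% of the probes had a log ratio beyond 3, with 46.3% below -3 on day 1 of H929 repeat 1 and 14.3% above 3 on day 4 of SKMM1 repeat 3. All 4 arrays of SKMM1 repeat 2 were of this kind. The median SD of a feature over courses was 0.82 with all arrays and 0.35 without these wide arrays.

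**Figure D1:**
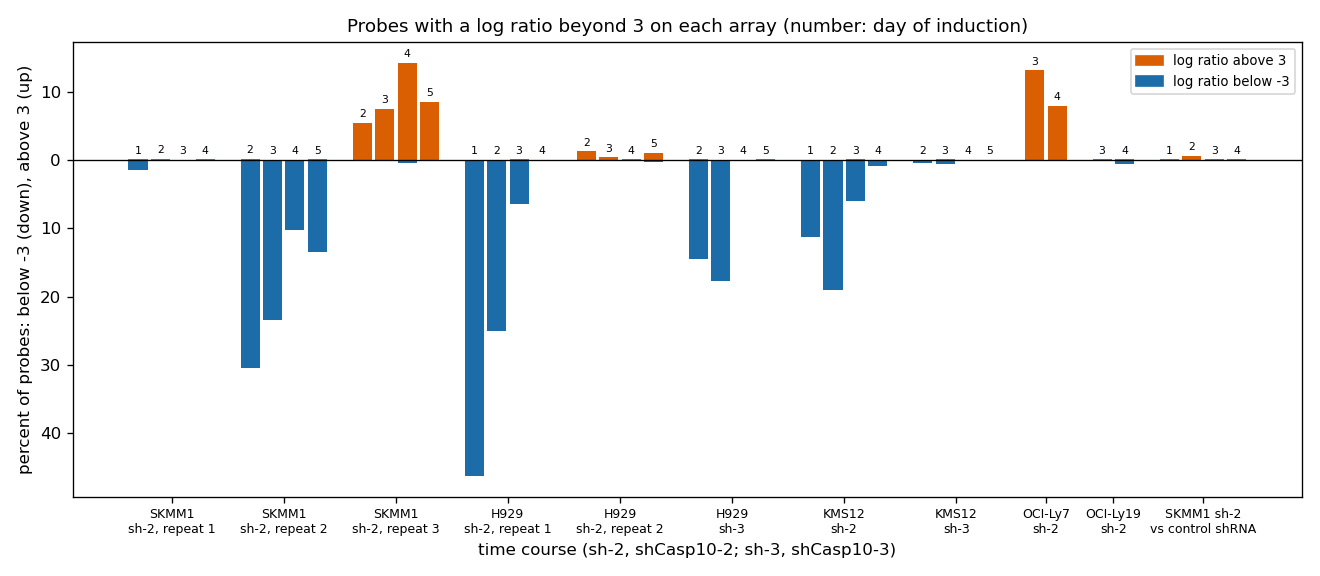
Percent of probes with a log ratio above 3 (upward bars) and below -3 (downward bars) on each of the 40 arrays, grouped by time course, with the day of induction above each bar. The share below -3 reached 46.3% on day 1 of H929 repeat 1, and the share above 3 reached 14.3% on day 4 of SKMM1 repeat 3.

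CASP10, the target of both hairpins, was below 0 on 29 of 32 myeloma arrays. Its mean over the 8 myeloma courses was -0.63 (SD 0.59, n = 8), with 7 of 8 courses below 0 (two-sided exact sign-flip test, p = 0.0156). With the wide arrays left out it was -0.25 (SD 0.19, n = 7), with 6 of 7 courses below 0 (exact sign-flip test, p = 0.0313). The limma fit over all features gave -0.61 (SE 0.24, adjusted p = 0.682) with all arrays. On single arrays that were not wide, CASP10 fell by 0.28 (SE 0.061, Benjamini-Hochberg adjusted p = 0.0254). It did not pass on course means without the wide arrays, at -0.27 (limma adjusted p = 0.272), or on single arrays when H929 repeat 1, either KMS12 course or SKMM1 repeat 1 was left out (highest adjusted p = 0.156). By course the mean ranged from -1.62 in SKMM1 repeat 2 and -1.42 in H929 repeat 1 to -0.08 in H929 repeat 2 and 0.01 in SKMM1 repeat 3. The direction of SKMM1 repeat 2 is not settled, and with its sign turned the limma fit of all arrays gave -0.25 (adjusted p = 0.999). Of the 6 CASP10 probes, 4 were below 0 in all 8 courses, with means from -0.98 to -0.77; the others disagreed, with means of -0.61 and 0.28 and 5 of 8 courses below 0 each. CASP10 was above 0 on both arrays labelled OCI-Ly7, at 1.77 (SD 0.39), and was -0.06 (SD 0.25) on the OCI-Ly19 arrays, so that the OCI-Ly7 label was not matched by a lower target level. Against the control shRNA, CASP10 in SKMM1 was -0.66 (SD 0.088, 3 arrays).

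**Figure D2:**
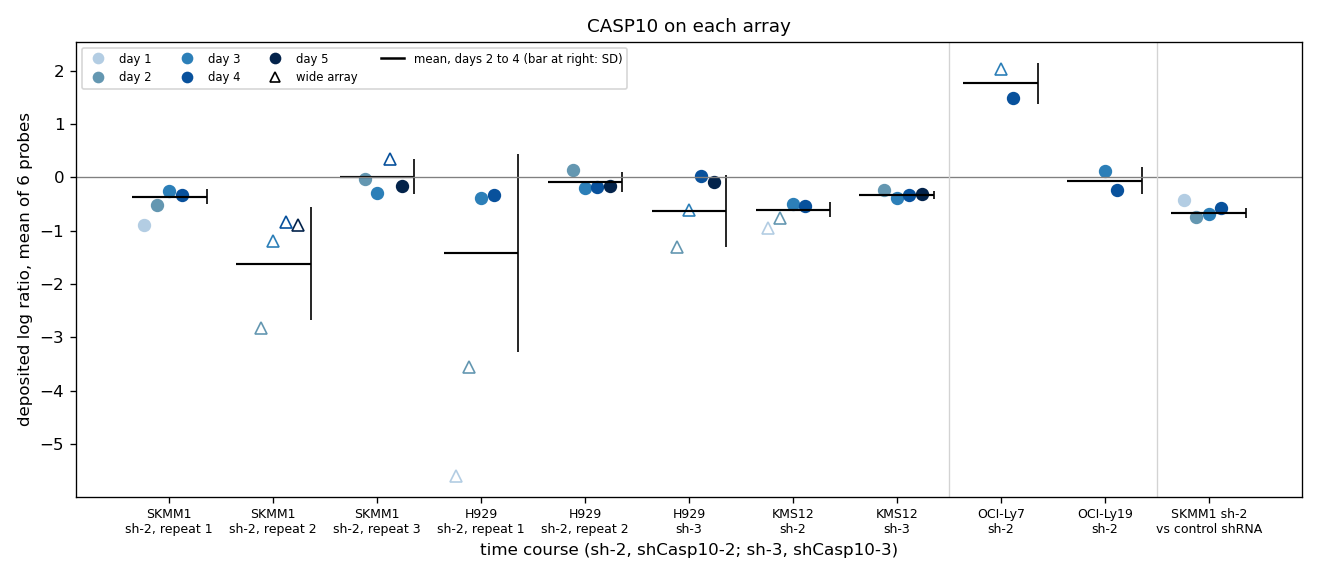
Deposited log ratio of CASP10, the mean of its 6 probes, on each array, by time course and day; triangles are wide arrays, horizontal lines are means over days 2 to 4 and the vertical bar at their right is the SD over those days. Points lie below 0 on 29 of 32 myeloma arrays and above 0 on both arrays labelled OCI-Ly7.

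With all arrays, no gene passed in the myeloma response. DUSP5, a nuclear phosphatase of ERK, had the smallest p, at -0.89 (SE 0.17) and below 0 in 8 of 8 courses. NUP210, a nuclear pore protein, was -0.48 (SE 0.11), COL7A1 -0.86 (SE 0.20) and PKM, the last enzyme of glycolysis, -0.47 (SE 0.12), each below 0 in 8 of 8 courses. UBE3C was -0.53, PARP16 -0.54, MUTYH -0.40 and UROS -0.41, also in 8 of 8 courses, and CLPP at -0.55 and ELP4 at -1.76 were below 0 in 7 of 8. limma called 0 of 9681 features after Benjamini-Hochberg adjustment (smallest adjusted p = 0.682), and 467 had an unadjusted p under 0.05, where chance gives 484. Of the features, 339 had the same sign in all 8 courses, 48 above 0 and 291 below 0, where chance gives 76 for independent courses; the median over all features was itself -0.27.

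When the wide arrays were left out and single arrays fitted, 442 features passed in limma, 139 higher and 303 lower, 191 of them named genes. Among named genes with 1 sign in 7 of 7 courses, the largest decrease was in DUSP5, which fell by 0.76 (SE 0.15, Benjamini-Hochberg adjusted p = 0.0221). Also lower were PKM at -0.51 (SE 0.12), ENO2, a glycolytic enolase, at -0.51 (SE 0.12), and SIAH2, a ubiquitin ligase that acts in the hypoxia response, at -0.52 (SE 0.11). COL7A1 was -0.60, BCR -0.58, NUP210 -0.54, MAN1A2 -0.53, PPHLN1 -0.52 and TIMP1, an inhibitor of matrix metalloproteinases, -0.51, all past the threshold with SE from 0.11 to 0.16. The genes that rose most were TMEM106C at 0.76 (SE 0.19), ISL1 at 0.73 (SE 0.13), HAL at 0.71 (SE 0.18), LDLRAD4 at 0.61 (SE 0.14), HLA-DOB at 0.60 (SE 0.12) and GATA1 at 0.60 (SE 0.092). ARHGAP4 rose by 0.58, ESYT2 by 0.55, IKBKG, a subunit of the IkB kinase, by 0.55 and TFF1 by 0.54. Each of these 10 higher genes was read by 1 probe. On lymphoma arrays that were not wide, PKM stood at -0.46 and NUP210 at -0.32, DUSP5 at 0.14, HAL at 2.46 and TFF1 at 2.27. Of these 20 genes 13 had the same sign there as in myeloma, while ENO2 at 0.24, TIMP1 at 0.85, BCR at 0.20, TMEM106C at -0.44, ARHGAP4 at -0.36 and GATA1 at -0.04 had, like DUSP5, the other.

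The number of calls changed with the setting and with the courses used. It was 0 on course means without the wide arrays (1444 features at an unadjusted p under 0.05), and on single arrays it was 0 without KMS12 with shCasp10-2, 9 without KMS12 with shCasp10-3 (4 higher, 5 lower), 17 without H929 repeat 1 (8 higher, 9 lower), 146 without H929 with shCasp10-3, 299 without SKMM1 repeat 1 (262 higher, 37 lower) and 794 without SKMM1 repeat 3. Of the courses left out, H929 repeat 1 and KMS12 with shCasp10-2 each kept a day 3 array with a negative tail. On these arrays 6.38% and 5.98% of probes were below -3, and the part of these tails in the calls was not tested. The arrays of SKMM1 repeat 3 ran opposite to those of repeat 2 (Pearson's r down to -0.517). On each array of repeat 3, 5 of the 6 CASP10 probes were below 0 and 1 was above. For this gene that argues against a turned sign, and no other gene was used to judge the direction of repeat 3. With its sign turned, limma called 0 on single arrays without the wide arrays in myeloma (989 at an unadjusted p under 0.05), 0 in SKMM1 (355) and 0 between SKMM1 and KMS12 (116), and 23 against the control shRNA, all lower; CASP10 was -0.23 (adjusted p = 0.377) and DUSP5 -0.48. Camera then called 0 lists without the wide arrays and 7 with all arrays (4 higher, 3 lower). Where calls were lost, DUSP5 and ISL1 stayed near their values with all 7 courses: without KMS12 with shCasp10-2, DUSP5 was -0.73 and ISL1 0.71, and without KMS12 with shCasp10-3 they were -0.79 and 0.76, none past the threshold.

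Among the gene lists, the glycolysis and hypoxia genes had the most members called. With all arrays, 21 of 23 measured members were below 0, and camera placed the list lower than other genes (adjusted p = 0.017; adjusted p = 0.838 with an estimated correlation; not past the threshold with median-centred arrays, adjusted p = 0.419). Its median of -0.24 was above the median of all features, -0.27, so the median and the test differed in sign. In the fit without the wide arrays, where calls were made, 4 members fell, 0 rose and 19 did not pass: PKM and ENO2 as above, SLC2A1, the main glucose transporter, at -0.45 (SE 0.11, adjusted p = 0.0299), and ADM, a hypoxia-induced peptide hormone, at -0.34 (SE 0.077, adjusted p = 0.0287), all below 0 in 7 of 7 courses. Adjusted over the list alone, 7 fell, with NDRG1, PGK1 and SLC2A3 added. Its camera test without the wide arrays gave adjusted p = 2.2e-04 (adjusted p = 1 with an estimated correlation) and 1.1e-04 with median-centred arrays (adjusted p = 0.714 with an estimated correlation). The list median lay below the array median in 7 of 7 courses, by a mean of -0.20 (SD 0.17, two-sided exact sign-flip p = 0.0156, adjusted over 24 lists 0.375). This is the smallest p that 7 courses can give, so 1 list alone could not pass after adjustment over 24 lists. The list median stood at -0.55 in SKMM1 repeat 1 and between -0.23 and -0.01 in the others. With all arrays it lay below in 4 of 8 courses, by a mean of -0.05 (SD 0.34; exact sign-flip p = 0.742), so no shift by course was shown there.

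**Figure D3:**
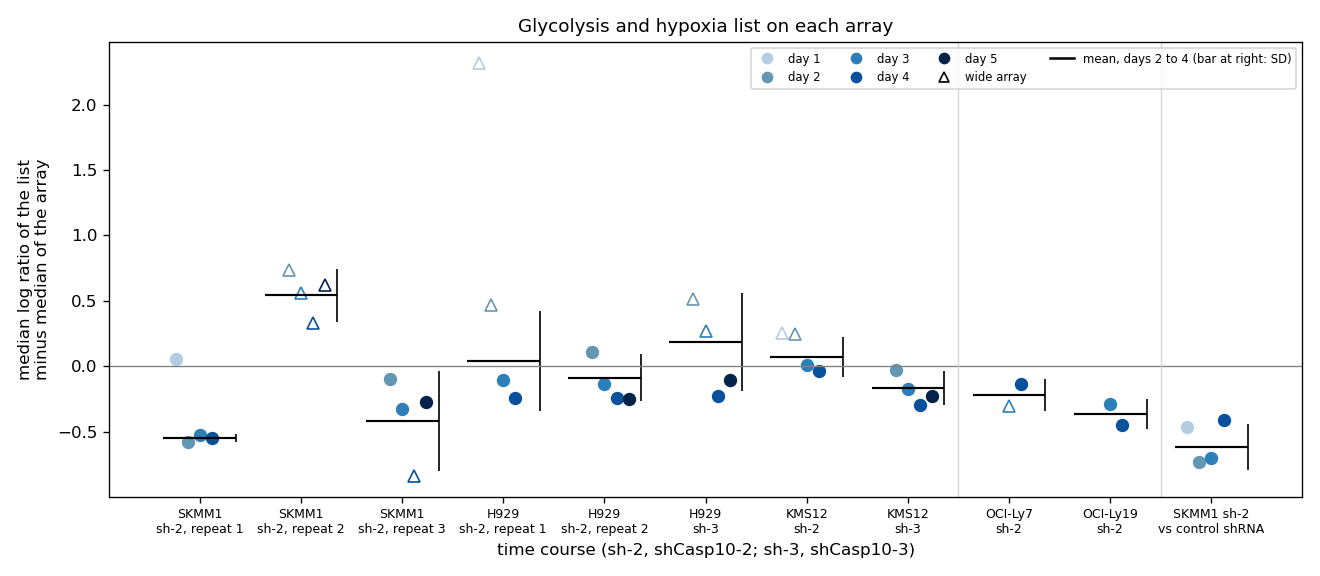
Median log ratio of the 23 measured glycolysis and hypoxia genes minus the median of the array, by time course and day; triangles are wide arrays, horizontal lines are means over days 2 to 4 and the vertical bar at their right is the SD. With wide arrays left out the course means lie below 0 in 7 of 7 myeloma courses, with all arrays in 4 of 8, and the 4 wide arrays of SKMM1 repeat 2 lie between 0.33 and 0.74.

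Other lists moved with the wide arrays. With all arrays, camera placed oxidative phosphorylation genes (9 of 10 members above 0, adjusted p = 5.3e-05) and ribosomal protein genes (13 of 20 above 0, adjusted p = 4.3e-04) higher than other genes and T and NK cell markers (16 of 16 below 0, adjusted p = 0.0035) lower. With an estimated correlation the adjusted p was 0.838, 0.838 and 0.891, and 0 lists passed fry (lowest adjusted p = 0.0758). The other 20 lists did not pass camera, the nearest being MYC targets (6 of 15 above 0, adjusted p = 0.0501). With median-centred arrays camera also called MYC targets (13 of 15 above 0, adjusted p = 0.0070) higher and mature B cell markers (18 of 19 below 0, adjusted p = 0.0070) and myeloid markers (9 of 9 below 0, adjusted p = 0.0245) lower, while with an estimated correlation the lowest adjusted p of any list was 0.55. Camera on all arrays called neither oxidative phosphorylation nor ribosomal protein genes when the sign of SKMM1 repeat 2 was turned. These 2 lists had camera adjusted p = 0.769 and 0.522 in the other direction once the wide arrays were left out. T and NK cell markers then had adjusted p = 0.0179 (adjusted p = 1 with an estimated correlation; 15 of 16 below 0), and NKG7, a granule protein of cytotoxic cells, fell by 0.43 (SE 0.11, limma adjusted p = 0.0374). Proliferation genes also passed (23 of 31 below 0, adjusted p = 0.0179; adjusted p = 1 with an estimated correlation), where with all arrays they had adjusted p = 0.797 in the other direction. Among them MCM2 at -0.38 (SE 0.070) and MCM7 at -0.30 (SE 0.072), subunits of the replicative helicase, were lower past the threshold, and 6 fell adjusted over the list alone. Proliferation genes were also lower in the lymphoma response without the wide arrays (24 of 31 below 0, camera adjusted p = 3.5e-05, 0.821 with an estimated correlation). Their median was -0.31 there and -0.13 in myeloma. T and NK cell markers were higher there (13 of 16 above 0, camera adjusted p = 0.0331, 0.837 with an estimated correlation).

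The study concerns autophagy, caspases and stress in myeloma, and few genes of those lists passed. In the myeloma response with all arrays, no gene of any list passed, adjusted over all features or over the list alone. In the caspase-10 and death receptor list (9 measured), without the wide arrays, CASP10 alone passed; CASP9 was -0.17 (SE 0.064) and FADD -0.16 (SE 0.070). Of 9 measured autophagy genes 0 passed, with BNIP3L, a mitophagy receptor, at -0.50 (SE 0.16, adjusted p = 0.0901), and of 13 BCL2 family genes 0 passed. Among 14 lysosomal genes HEXA rose by 0.45 (SE 0.098), and adjusted over the list alone 1 rose and 1 fell, CD63. Of 20 amino acid and stress response genes, SLC3A2, the heavy chain of an amino acid transporter, fell by 0.31 (SE 0.084) and CBS was lower at -0.26 (SE 0.067), and 4 fell adjusted over the list alone, with CEBPB and SLC7A5 added. Of 21 unfolded protein response genes, HSPA5, the chaperone BiP, fell by 0.29 (SE 0.073) and MANF was lower at -0.28 (SE 0.073). In the lymphoma response without the wide arrays, camera placed amino acid and stress genes (adjusted p = 9.8e-05) and unfolded protein response genes (0.0019) lower. With an estimated correlation both had adjusted p = 0.821. The list medians were -0.45 and -0.38 there and -0.09 and -0.06 in myeloma. In myeloma, SC5D rose by 0.26 (SE 0.070) among 12 cholesterol and fatty acid genes, and 1 rose and 2 fell, SREBF2 and FASN, adjusted over that list alone. No member passed, over all features or over the list alone, among FOXO targets (15 measured), p53 targets (16), MYC targets (15), ribosomal proteins (20), proteasome (8), oxidative phosphorylation (10), heat shock (7), IRF4 and plasma cell genes (15), NF-kB targets (20), interferon response (26), histones (9), mature B cell markers (19), myeloid markers (9) or erythroid and platelet markers (5). IRF4 itself was -0.14 and MYC -0.12.

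In the separate lines, SKMM1 had the most calls on single arrays without the wide arrays, and 0 on course means (2397 at an unadjusted p under 0.05 in limma, smallest adjusted p = 0.172). The largest decreases were in DUSP5 at -1.22 (SE 0.27), PPP1R18 at -1.16 (SE 0.16), TRAF3IP3 at -1.15 (SE 0.21), MXRA7 at -1.08 (SE 0.29) and LGALS1, a galectin, at -0.96 (SE 0.20). WDFY4 rose by 3.55 (SE 0.73), SGPP1 by 3.40 (SE 0.84), MST1R by 3.35 (SE 0.77), EPS15L1 by 3.23 (SE 0.95) and EFCAB13 by 3.19 (SE 0.68), each read by 1 probe. On the lymphoma arrays that were not wide, WDFY4 stood at 3.02, SGPP1 at 2.49, MST1R at 2.86, EFCAB13 at 2.96 and EPS15L1 at 0.97. Arrays that were kept also had positive tails. Probes above 3 made up 5.48% and 7.48% on days 2 and 3 of SKMM1 repeat 3 and 7.95% on day 4 of OCI-Ly7. They made up at most 0.18% on days 2 to 4 of SKMM1 repeat 1. The part of these tails in the rises was not tested. limma called 1130 features (805 higher, 325 lower) from 5 arrays of 2 courses, 231 without repeat 3 (59 higher, 172 lower), 983 without repeat 1 (943 higher, 40 lower), 401 without H929 repeat 2 and 168 without KMS12 with shCasp10-3; on median-centred arrays 749 were higher and 925 lower, so the balance of directions changed with the course left out and with the centring. In H929 limma called 0 (593 at an unadjusted p under 0.05), with FLT3LG at -0.64 (SE 0.13), COX15 at -0.72 (SE 0.16) and GPX1 at 0.48 (SE 0.11). In KMS12 it called 0 (958 at an unadjusted p under 0.05), with ID1 at -0.49 (SE 0.097), GPS2 at -0.95 (SE 0.19) and NCOA4 at -0.66 (SE 0.14). With all arrays limma called 0 in each line, with 246, 151 and 77 features at an unadjusted p under 0.05 in SKMM1, H929 and KMS12; the smallest p were those of LGALS1 at -1.03 (SE 0.21) in SKMM1, RPP25 at -1.67 (SE 0.39) in H929 and RFX1 at -1.43 (SE 0.41) in KMS12.

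A difference between lines passed for few genes, and the kept arrays of SKMM1 repeat 3 had the positive tail given above. The kept day 3 array of KMS12 with shCasp10-2 had a negative tail, with 5.98% of probes below -3. The part of these tails in the differences was not tested. SKMM1 stood above KMS12 without the wide arrays in WDFY4 by 5.62 (SE 1.04), PHF20L1 by 2.93 (SE 0.48), QSOX2 by 1.81 (SE 0.33), AEN, a p53-induced nuclease, by 1.66 (SE 0.29) and CYBB, a subunit of the phagocyte NADPH oxidase, by 1.66 (SE 0.32), and below it in COTL1 at -1.09 (SE 0.18); limma called 20 features in this difference on single arrays and 0 on course means without the wide arrays (1877 at an unadjusted p under 0.05, smallest adjusted p = 0.241). On single arrays it called 0 between SKMM1 and H929, with PHF20L1 at 2.74 (SE 0.46) and SCFD1 at 1.22 (SE 0.23) not past the threshold (1674 at an unadjusted p under 0.05), and 0 in the F-test over the 3 lines (1742 at an unadjusted p under 0.05). With all arrays it called 0 in each (75, 40 and 31 at an unadjusted p under 0.05); ID3 at -0.86 (SE 0.23), PRPF38B at 1.55 (SE 0.43) and RPP25 at 1.78 (SE 0.56) had the smallest p between SKMM1 and H929.

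The lymphoma lines served as controls, and in the difference from them a dye effect common to all arrays cancels. MYC target genes stood higher in the myeloma response than in the lymphoma response: 13 of 15 members were above 0, with a median difference of 0.61, where the median of all features was -0.37. MYC itself was 1.52 (SE 0.51), NOP56 1.57 (SE 0.71) and DDX21 0.95 (SE 0.44), none past the threshold singly. In the lymphoma lines 14 of 15 of these genes were below 0, with a median of -0.64. CASP10 was -1.24 (SE 0.48, adjusted p = 0.639), a difference drawn in part from the arrays labelled OCI-Ly7, where it was above 0. ZSCAN18 at -1.81 (SE 0.33), CELA3A at -1.85 (SE 0.34) and PGAM2 at -1.33 (SE 0.25) had the smallest p, and in the lymphoma response ZSCAN18 was 1.65 (SE 0.30) and RAB33B 1.06 (SE 0.21). limma called 0 features (654 at an unadjusted p under 0.05) and 0 in the lymphoma response (836 at an unadjusted p under 0.05), and it called 82 in the difference when OCI-Ly19 was left out. By camera, MYC targets (adjusted p = 1.4e-06), amino acid and stress response (1.3e-04), ribosomal proteins (1.3e-04), oxidative phosphorylation (1.3e-04), proliferation (9.9e-04) and unfolded protein response (0.0011) were higher and T and NK cell markers lower (9.9e-04), each with adjusted p = 0.516 with an estimated correlation; of the T and NK markers 2 were lower adjusted over the list alone. Without the wide arrays ribosomal proteins did not pass (adjusted p = 0.159), and the other 6 lists passed in the same direction (highest adjusted p = 0.0353), each with adjusted p = 0.992 with an estimated correlation. Within the runs of database numbers that held both kinds of line, the MYC target difference was 2.02 for SKMM1 repeat 2 minus OCI-Ly19 and -0.43 for SKMM1 repeat 3 minus OCI-Ly7, relative to the array medians, so it did not keep its sign within runs; the T and NK cell marker difference was -0.43 and -1.60 and that of CASP10 -0.95 and -1.74. The difference in glycolysis and hypoxia genes did not pass (adjusted p = 0.49), and in the lymphoma response camera placed the list lower (adjusted p = 0.0075; adjusted p = 0.659 with an estimated correlation).

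The 2 hairpins were compared in H929 and KMS12. CASP10 was -0.48 (SE 0.57) with shCasp10-3 and -0.68 (SE 0.49) with shCasp10-2, a difference of 0.20 (SE 0.76). On single arrays without the wide arrays it was -0.15 with shCasp10-3 and -0.36 with shCasp10-2. H929 with shCasp10-3 then kept 1 array, where CASP10 was 0.025. GSTA2 at -2.28 (SE 0.36), PDCD4 at -1.996 (SE 0.39) and HIBADH at -2.18 (SE 0.44) had the smallest p for shCasp10-3 minus shCasp10-2. limma called 0 features (279 at an unadjusted p under 0.05). It called 1 unnamed feature without the wide arrays, where FAM200B was -2.24 (SE 0.32, adjusted p = 0.0504). Apart from shCasp10-2 in H929, each line and hairpin had 1 course, which was assumed to vary like the others.

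The change from day 2 to day 4 asked whether responses grew with time. MBTD1 was 3.46 (SE 0.72), GHRL 3.39 (SE 0.76), CD8B, a T cell marker, 2.08 (SE 0.47) and CASP10 0.78 (SE 0.43), none past the threshold. limma called 0 features, with 1066 at an unadjusted p under 0.05, 1038 of them above 0. With the wide arrays left out it called 0 (602 at an unadjusted p under 0.05), and PGK1, a glycolytic kinase, had the smallest p at -0.34 per day (SE 0.062). A slope over all days called 1134 (1033 rising, 101 falling) with all arrays and 0 without the wide arrays (990 at an unadjusted p under 0.05).

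Against the control shRNA both channels held induced cells, so that doxycycline was shared by both. On single arrays, with the wide arrays of the other courses left out, TRAF3IP3 was -2.08 (SE 0.27), UBE2L6, an enzyme of ISG15 conjugation, -1.84 (SE 0.25), CKLF, a chemokine-like factor, -1.82 (SE 0.24), DOCK2, an activator of Rac in lymphocytes, -1.76 (SE 0.47) and LGALS1 -1.68 (SE 0.25), all lower in limma (highest adjusted p = 0.0301). S1PR1 rose by 1.98 (SE 0.54), PHF20L1 by 1.57 (SE 0.44), SPAG1 by 1.44 (SE 0.43), ALCAM by 1.40 (SE 0.41) and IVD by 1.38 (SE 0.31). DUSP5 at -1.39, PKM at -1.26 and ENO2 at -1.33, looked up here because of the myeloma response, also passed, and CASP10 fell by 0.66 (SE 0.14, adjusted p = 0.0095). limma called 781 features (122 higher, 659 lower) on single arrays without the wide arrays, 488 when KMS12 with shCasp10-3 was left out and 492 without H929 repeat 2, and 0 with all arrays (321 at an unadjusted p under 0.05). On course means without the wide arrays it also called 0 (1342 at an unadjusted p under 0.05, smallest adjusted p = 0.108), and CASP10 had adjusted p = 0.297. This is 1 course, whose spread was taken from the other courses, and its Cy5 RNA may be that of SKMM1 repeat 1.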

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

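The tests of a single course carrying the calls, of wide arrays behind the glycolysis genes and of an effect of dyes or doxycycline on those genes were chosen only after the results were seen, and so was every fit without the wide arrays.

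Single courses stood apart from the others in 9 of 50 groups of course values tested, where chance gives about 1 in 20. The values are medians of a gene list relative to the array median. With all arrays, SKMM1 repeat 2, all of whose arrays were wide, stood at -0.59 for the caspase-10 and death receptor list (others -0.23 to 0.01), at -0.77 for FOXO targets (others -0.20 to 0.02), at -0.66 for p53 targets (others -0.17 to 0.19), at -1.14 for the interferon response (others -0.46 to 0.0014) and at 0.28 for IRF4 and plasma cell genes (others -0.02 to 0.07). SKMM1 repeat 3 stood at -0.28 for the BCL2 family (others -0.06 to 0.14). Without the wide arrays, SKMM1 repeat 1 stood at -0.55 for glycolysis and hypoxia genes (others -0.23 to -0.01) and at -0.24 for heat shock genes (others -0.02 to 0.09), and SKMM1 repeat 3 at 0.85 for erythroid and platelet markers (others -0.09 to 0.19).

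Some differences between lines passed a test of the difference itself. Between the myeloma and the lymphoma response, camera gave adjusted p = 1.4e-06 for MYC targets, 1.3e-04 for amino acid and stress response genes, 1.3e-04 for ribosomal proteins, 1.3e-04 for oxidative phosphorylation, 9.9e-04 for proliferation, 0.0011 for the unfolded protein response and 9.9e-04 for T and NK cell markers, each with adjusted p = 0.516 with an estimated correlation. Ribosomal proteins did not pass without the wide arrays (adjusted p = 0.159). Between SKMM1 and KMS12, limma called 20 features on single arrays without the wide arrays and 0 on course means (1877 at an unadjusted p under 0.05). For SKMM1 minus H929 the real count was 0, which each of the 10 splits of the 6 courses into 3 and 3 reaches whatever the data, so the splits decide nothing; the highest other count was 32.

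The 442 features called in the myeloma response without the wide arrays, DUSP5 and PKM among them, were weighed first. Only 1 of 64 sign patterns of the 7 courses, the one as deposited, gave as many. The highest other count was 134, with the sign of H929 repeat 2 turned. The flips were run only in this setting, which was chosen after seeing the data, with the correlation held at that of the real fit. Course means of the same arrays called 0, as did single arrays with the sign of SKMM1 repeat 3 turned. Chance is therefore not excluded. Leaving out each of 4 courses in turn brought the count to under 1 in 1.5 of the full one (0 without KMS12 with shCasp10-2, 9 without KMS12 with shCasp10-3, 17 without H929 repeat 1, 146 without H929 with shCasp10-3), which may reflect the loss of arrays as well as the weight of a course. On the lymphoma arrays that were not wide, the called features, signed as in myeloma, had a median of 31.3% (OCI-Ly7 day 4), 63.6% (OCI-Ly19 day 3) and 99.5% (OCI-Ly19 day 4) of that in myeloma, so an effect of dyes or doxycycline shared with the lymphoma lines stays open; CASP10 was not clearly lower on those arrays (1.497 on day 4 of OCI-Ly7, -0.06 over the 2 arrays of OCI-Ly19). A response to the loss of CASP10 stays open as well, untested by an array with a control shRNA against uninduced cells.

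The lower glycolysis and hypoxia genes, such as PKM, ENO2 and SLC2A1, were seen without the wide arrays, so that the list lying below the array median in all 7 courses there restates the pattern (SKMM1 repeat 1 at -0.55, the others -0.23 to -0.01); with all arrays it did so in 4 of 8 courses, and the part of the wide arrays stays open. On the lymphoma arrays that were not wide the list lay at 65%, 140% and 219% of its myeloma mean, which is consistent with a cause shared by both kinds of line, such as a dye effect or doxycycline. On the 4 arrays of SKMM1 against the control shRNA, where both channels held induced cells, the list lay between -0.73 and -0.41, so that doxycycline alone is an unlikely cause there while a dye effect is not excluded. A response to the knockdown stays open.

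With all arrays, oxidative phosphorylation and ribosomal protein genes stood higher and T and NK cell markers lower in myeloma. Over 10 courses, the difference between these lists followed the skew of the tails, with Pearson's r = -0.871 (permutation p = 9.3e-04) and Spearman's rho = -0.891 (permutation p = 0.0011), 1 relation tested, and r = -0.793 without the 2 courses farthest in skew. These lists were taken up because camera called them with all arrays, and skew and difference come from the same values. The permutation p does not allow for that choice. The difference was above 0 on 10 of 10 wide arrays with a negative tail (0.93 to 4.91); of the 2 with a positive tail it was -1.55 on day 3 of OCI-Ly7 and 0.15 on day 4 of SKMM1 repeat 3, so the test stays undecided. A candidate explanation is that genes of low expression, T and NK cell markers probably among them, make up the tails, as ratios of dim spots would; no intensities were held to test it.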

How the results depend on the processing

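Fits without the wide arrays, with array weights, over features within 2 of 0, with crossed repeat numbers, with turned signs and by sign flips of the list median were chosen after seeing the data. With the sign of SKMM1 repeat 3 turned, the calls without the wide arrays were 0 in myeloma (989 at an unadjusted p under 0.05 in limma), 0 in SKMM1 (355) and 23 against the control shRNA. Turning repeat 2 with all arrays gave 2497 features at an unadjusted p under 0.05 in SKMM1, where the deposited sign gave 246. Both gave 0 calls. Of 147 alternatives of the 10 planned counts, 137 gave 0 calls, as did 81 of 82 fits that left out 1 course. The exceptions were a slope over all days with 1134 features; the fits on single arrays without the wide arrays, with 442 in myeloma, 1130 in SKMM1, 781 against the control shRNA, 1 for myeloma minus lymphoma and 1 between hairpins; array weights, with 1742 in myeloma (465 higher) and 148 for myeloma minus lymphoma; features within 2 of 0 on every array, with 57 of 2217 in myeloma; and myeloma minus lymphoma with a course left out, from 0 (without SKMM1 repeat 3, among others) to 82 (without OCI-Ly19). Turned signs apart, CASP10 was below 0 in 23 of 23 alternatives, from -0.73 to -0.27 (limma adjusted p from 0.0059 to 0.988). It passed in 2, at -0.28 without the wide arrays and -0.28 with array weights. With the sign of SKMM1 repeat 2 turned it was -0.25 in myeloma and 0.42 in SKMM1 with all arrays. With that of repeat 3 turned it was -0.61 in myeloma with all arrays and -0.23 without the wide arrays. None of these 4 passed. The cause was not tested for any of these alternatives. The spread was narrower without the wide arrays, but course means of the same arrays called 0 in myeloma, in SKMM1 and against the control shRNA. Those calls thus also rested on fitting the days of a course as single arrays. Without the wide arrays, leaving out a course gave 0 (KMS12 with shCasp10-2) to 794 (SKMM1 repeat 3) calls in myeloma, 168 (KMS12 with shCasp10-3) to 1152 in SKMM1, 488 to 1042 against the control shRNA, and -0.32 to -0.24 for CASP10, past the threshold in 4 of 8 alternatives. An adjusted p of 0.01 left 4, 10 and 208 calls in myeloma, in SKMM1 and against the control shRNA, median centring gave 617, 1674 and 986, and single probes gave 891 in myeloma. The 20 named genes kept their sign in 160 of 160 alternatives, passed in 66, and all 20 passed when median-centred; 0 passed in every one. Of the gene lists, 0 passed with an estimated correlation, 0 with fry and 0 with sign flips of the list median. With so few courses 1 list alone could not pass the sign flips after adjustment, so that 0 decides little. By camera 7 passed for myeloma minus lymphoma and 3 without the wide arrays. In myeloma minus lymphoma, camera placed glycolysis and hypoxia genes higher than other genes, not past the threshold (adjusted p = 0.49). That is another comparison, and the list was lower in the lymphoma response too, so it is no reversal of the myeloma response. Without the wide arrays the camera direction reversed for proliferation (adjusted p = 0.0179), ribosomal proteins (0.522) and oxidative phosphorylation (0.769), and the cause was not tested. Between SKMM1 and H929 the replicate block gave 0 calls with limma (3 at an unadjusted p under 0.05 without the block, 1 with it); the 2 pairs of repeats had a correlation of -0.603, and the crossed pairing gave 0 calls (47 at an unadjusted p under 0.05). The run of database numbers as a random block gave 0 calls for myeloma minus lymphoma and could not be fitted in myeloma, where 1 run held over 1 course. A filter on missing values moved nothing, since there were none. Signal over background, which limits ratios of dim spots, is unknown.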

Other observations

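The genes given here for the comparison with the control shRNA were chosen only after the results were seen. Days 1 and 5 entered none of the main comparisons, only alternatives over all days. On day 1 CASP10 averaged -2.48 (SD 2.70) over 3 myeloma arrays, of which 1 was not wide, at -0.89. On day 5 it averaged -0.33 (SD 0.33) over 5 arrays, and -0.18 (SD 0.094) over the 4 that were not wide. On the 4 arrays of SKMM1 against the control shRNA, the glycolysis and hypoxia genes relative to the array median were -0.47, -0.73, -0.70 and -0.41 on days 1 to 4. In that comparison the mean over days 2 to 4 was -1.26 for the glycolytic kinase PGK1, -1.59 for NDRG1, a hypoxia-induced gene, -1.45 for TIMP1, -0.70 for the chaperone HSPA5, -0.66 for the helicase subunit MCM2 and -0.59 for FADD, the adaptor of caspase-8 and caspase-10. These are values of 1 course, given with no test; on course means limma called 0 features in this comparison (1342 at an unadjusted p under 0.05 without the wide arrays).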
